A study of Mus musculus with 18 samples.

How the data were processed

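Total RNA of 18 mouse brain hemispheres was labelled with biotin and hybridised to single-channel Affymetrix whole-genome arrays, 1 array per sample, per the labels. The groups were taken from the sample titles, which give the genotype and the age in weeks of each sample. They placed 3 wild-type and 3 transgenic samples at 18 weeks, 3 and 2 at 22 weeks, and 3 and 4 at 27 weeks. The design text of the series states 3 samples per genotype and age, so the titles and the design text disagree on 1 transgenic sample. The titles were followed, and each of the 4 transgenic samples titled 27 weeks was moved to 22 weeks in turn as an alternative. Each title carries a number of its own, and the samples were treated as separate mice.

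The deposited table holds linear signal intensity values, 1 per probe set and array, as the authors scaled them. The labels name MAS5, whose version is not given in the sources used here, and the table held no detection calls. The 2% trimmed mean was 100 on every array, so no further scaling was applied. No 2 arrays held identical values, and the correlation of log2 values between pairs of arrays ranged from 0.952 to 0.98. Because an array has no read depth, the number of mice and the height of a signal above background limit the precision.

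The table held 45101 probe sets, of which 64 control probe sets were left out. The annotation given with the series named 1 gene for 34945 of the others, several genes for 932 and none for 9160. Symbols of 34741 probe sets were checked through their Entrez identifiers, and 18193 genes had at least 1 probe set. Probe sets with several genes or none were tested and counted but not named. No genome build was used, and no coordinates are given.

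The offset, the filter, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Values were transformed as log2(signal + 5.4), where 5.4 is the 20th percentile of all values. Probe sets whose mean over all 18 samples exceeded the 40th percentile of those means, a signal of 16.1, were kept, which left 27022 probe sets and 12582 genes. A fold change is therefore on the log2(signal + 5.4) scale and understates the change of weak probe sets. One linear model with a mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in intensity. All 6 groups shared 1 estimate of the spread. The contrasts were transgenic minus wild-type averaged over the 3 ages, the same difference at each age, the dependence of that difference on age as a moderated F-statistic, and the effect of age within each genotype as a moderated F-statistic. Adjusted p-values follow Benjamini and Hochberg over the probe sets tested, with a threshold of 0.05 and no fold minimum. Means and SDs are of the signals, and the standard error of a log2 fold change is written SE.

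A gene is represented by its probe set with the highest mean among those kept. The genes named are the 12 with the largest fall and the 12 with the largest rise in the mean over ages that passed the threshold and kept 1 direction at all 3 ages. At each age they are the 5 largest falls and 5 largest rises among genes past the threshold whose mice do not overlap between genotypes. For the interaction and the tests of age they are the 5 genes with the smallest adjusted p, and for each gene list the 4 members with the smallest p in the mean over ages. Htt and the genes specific to a sex are always given. Other genes named were chosen after their values were seen, and the text says so.

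The 25 gene lists cover striatal medium spiny neuron genes, immediate early genes, neuropeptides, receptors, channels, metabolic and protein-handling genes, and markers of cell types and brain regions that a hemisphere can hold. Each list was tested on 1 probe set per gene with camera from limma at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. The test with an estimated correlation and fry, which asks whether the members of a list move on balance 1 way, served as alternatives. Lists of 5 genes specific to a sex and of Htt alone were checks and were not tested as lists. Some genes are members of several lists.

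The fit was tested on simulated data made from the real means and residual spreads, with 200 of 27022 probe sets changed in 5 simulations per comparison. For the mean over ages it recovered 26.9% of changes of 0.3 log2 units, 75.5% of changes of 0.6 and 94.8% of changes of 1. At single ages the recovery of a change of 0.6 was 39.1% at 18 weeks, 27.5% at 22 weeks and 38.2% at 27 weeks. For the interaction, 40% of changes of 1 log2 unit were recovered. The share of false calls lay between 4.5% and 7.9%. In a simulation of 20 lists of 25 genes, camera recovered all 5 lists shifted by -0.3 and called 0 of the others. The simulated genes varied independently of each other, whereas the estimated correlation in the real striatal list was 0.33. The simulation therefore does not test the preset correlation.

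The alternatives were the offset divided and multiplied by 4, no filter and a filter at the 60th percentile, quantile normalization, variances without the trend, array weights, a 1.5-fold minimum, 1 probe set per gene, each sample left out in turn, the mice of 1 age alone, an additive model and the moved age labels. After the data were seen, fits were added without 3 wild-type samples with Gabra6 signals below 100, with a term for these 3 samples, and without 2 transgenic samples with growth hormone signals above 300. A list of 48 interferon-stimulated genes was also written after the data were seen.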

Results

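Gene expression was measured in brain hemispheres of R6/1 mice and of their wild-type littermates aged 18, 22 or 27 weeks. The R6/1 line is a mouse model of Huntington's disease that carries exon 1 of the human huntingtin gene with an expanded CAG repeat. The 18 arrays comprised 9 wild-type and 9 transgenic mice, with 3 wild-type mice at each age and with 3, 2 and 4 transgenic mice at 18, 22 and 27 weeks as titled. The median signal per array ranged from 25.5 to 29.3 around a trimmed mean of 100. The ratio of 3′ to 5′ Gapdh signal, a measure of RNA integrity, was 0.728 ± 0.031 (SD, n = 9) in transgenic and 0.724 ± 0.02 (SD, n = 9) in wild-type mice (two-sided exact permutation p = 0.762).

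The samples differed in the brain regions they contained. Gabra6, a GABA receptor subunit of cerebellar granule cells, had signals of 10.9 in 18-week wild-type replicate 1 and of 9.9 and 0.6 in 22-week wild-type replicates 2 and 3, against 936 to 1579 in the other 15 samples. Pcp2, a Purkinje cell gene, had signals of 18.6, 9.6 and 2.5 in those 3 samples. Cdhr1, a gene of olfactory bulb projection neurons, reached 291 and 283 in the first 2 of these samples and 25.3 to 77.4 in the other 16. Growth hormone, a pituitary transcript, had signals of 558 and 1019 in 27-week transgenic replicates 2 and 3, against at most 144 in the other 16 samples. Prl, another pituitary hormone transcript, had signals of 17.6 and 79.5 in those 2 samples. It was highest, at 261.5, in 18-week wild-type replicate 2, the sample with the growth hormone signal of 144. No transgenic sample and no 27-week sample was low in Gabra6, and counts are therefore also given without the 3 wild-type samples. The mean log2 level of the 5 measured HOX genes, relative to the mean of all samples, was -0.91, -0.92 and -1.24 in those 3 samples. It was also low in 18-week transgenic replicate 3 (-1.16) and 18-week wild-type replicate 3 (-0.70), against 0.01 to 0.80 in the others. Leaving out the 3 samples therefore does not make the rest alike in these genes.

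**Figure D1:**
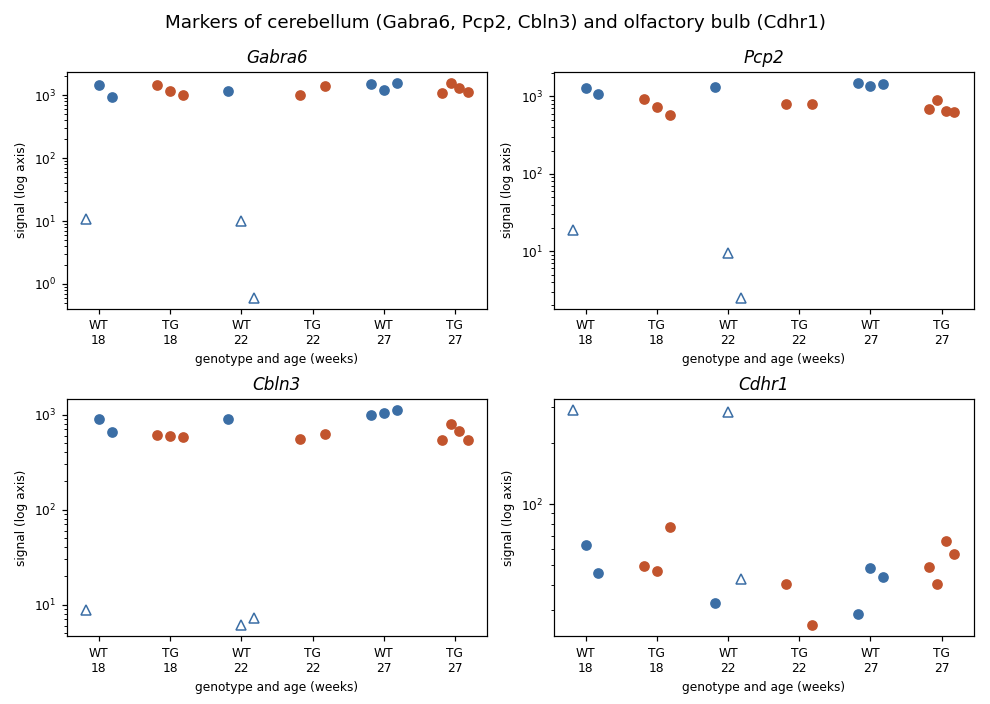
Array signal on a log axis of 3 cerebellar genes and 1 olfactory bulb gene in each mouse (blue, wild-type, WT; orange, transgenic, TG), by genotype and age in weeks. Open triangles are the 3 wild-type samples with Gabra6 signals of 10.9, 9.9 and 0.6, which also have the lowest Pcp2 and Cbln3 signals.

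Sex-specific transcripts split the mice clearly. Xist, the RNA that coats the inactive X chromosome, had signals of 495 to 2397 in 6 mice whose Y-linked Eif2s3y signal was at most 6.4, and of 4.6 to 22.1 in 12 mice whose Eif2s3y signal was 101 to 183. Kdm5d and Uty, both Y-linked, followed the same split, and Ddx3y was not in the annotation given. Each of the 6 groups held 1 female by these markers, beside 3 males in the 27-week transgenic group, 1 in the 22-week transgenic group and 2 in each of the others, while the labels call the mice matched for sex. Htt had signals of 109 ± 26.0 (SD, n = 9) in wild-type and 125 ± 38.3 (SD, n = 9) in transgenic mice, a log2 fold change of 0.18 ± 0.15 (SE, adjusted p = 0.46). One array, 18-week transgenic replicate 3, stood apart, with an Htt signal of 224 against 73.5 to 156 in the others, a score of -35.9 on the second principal component against -17.3 to 25.4, and an array weight of 0.37 against 0.606 to 1.46. Arrays of this kind probe the 3′ end of a transcript, so this value does not measure the transgene.

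The first comparison asked which transcripts differed between transgenic and wild-type hemispheres over all 3 ages. Transgenic hemispheres had lower levels of transcripts for neuropeptides, for striatal signalling proteins and for proteins induced by neuronal activity. The largest fall was in Pmch, the precursor of melanin-concentrating hormone made in the lateral hypothalamus, with signals of 469 ± 101 (SD, n = 9) in wild-type and 111 ± 23.2 (SD, n = 9) in transgenic mice, a 3.99-fold difference (log2 fold change -2 ± 0.10 SE, limma with Benjamini-Hochberg adjusted p = 2.4e-09). Penk, the enkephalin precursor of striatal projection neurons, fell from 966 ± 141 to 359 ± 34.7 (SD, n = 9 each, 2.67-fold, adjusted p = 9.7e-10). Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, fell from 450 ± 64.1 to 162 ± 24.2 (2.73-fold, adjusted p = 2.2e-08). For Pmch, Penk and Ppp1r1b all 9 transgenic mice lay below all 9 wild-type mice.

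The other genes with the largest falls were Avp, the vasopressin precursor (3.43-fold), Arc, a synaptic protein induced by activity (3.05-fold), Slc6a3, the dopamine transporter (2.98-fold), and Egr2, an immediate early transcription factor (2.85-fold). Dusp5, an activity-induced phosphatase of the MAP kinase ERK (2.74-fold), Lrrc10b (2.74-fold), Vip, the precursor of vasoactive intestinal peptide (2.54-fold), Trh, the precursor of thyrotropin-releasing hormone (2.52-fold), and the probe set annotated to Mir1931 (2.54-fold) completed the 12. Their adjusted p-values ran from 6.7e-09 for Vip to 0.013 for Mir1931. All 9 transgenic mice lay below all wild-type mice for Avp, Arc, Slc6a3, Lrrc10b, Vip and Trh. That held for 8 mice for Egr2, 4 for Mir1931 and 3 for Dusp5. Without the 3 wild-type samples low in Gabra6 the log2 fold changes of Avp, Arc and Egr2 were -1.53, -1.30 and -1.31. The falls of the genes in this paragraph were then smaller than with all samples, except that of Dusp5, which was larger.

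**Figure D2:**
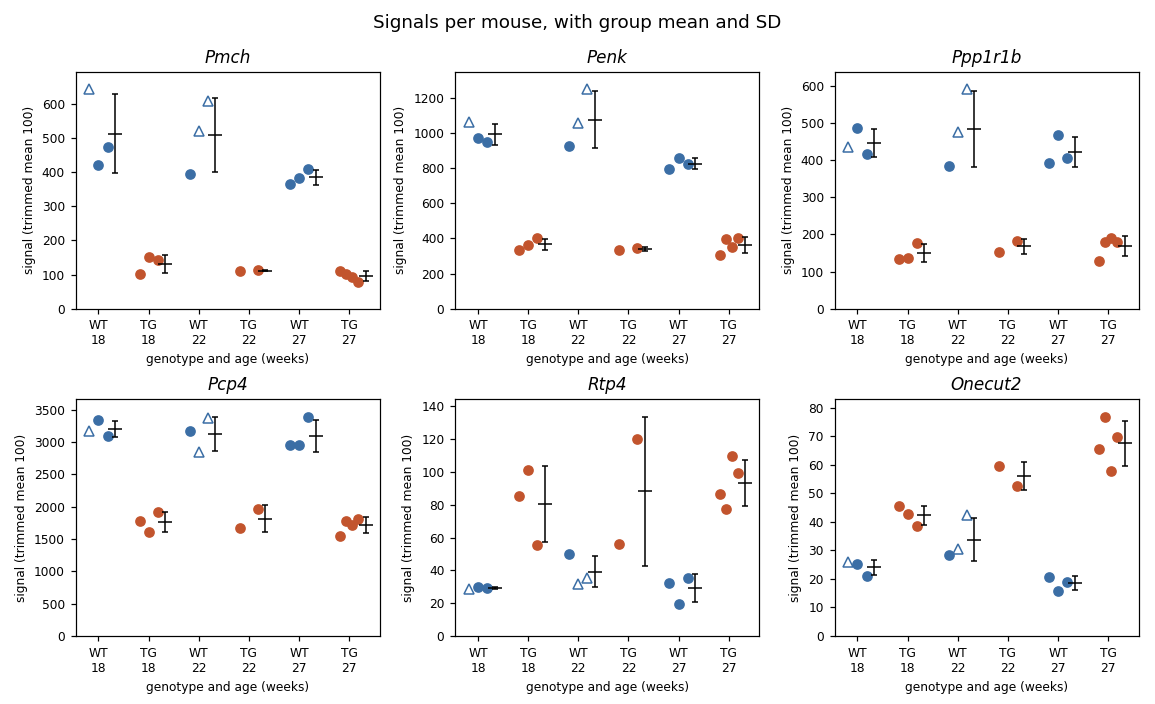
Array signal of 6 genes in each mouse (blue, wild-type, WT; orange, transgenic, TG), by genotype and age in weeks, with the mean and SD of each group as black bars. Open triangles are the 3 wild-type samples low in Gabra6. Pmch, Penk, Ppp1r1b and Pcp4 lie lower in all 9 transgenic mice than in any wild-type mouse, and Rtp4 lies higher.

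The 12 largest rises were in weakly expressed genes, with mean wild-type signals of 11.2 to 34.3. They included 4 genes known to be induced by interferon. Ifi27l2a rose 2.55-fold (adjusted p = 0.0061), Rtp4 2.41-fold (adjusted p = 2.2e-05), Oasl2 2.13-fold (adjusted p = 5.5e-05) and Usp18, which encodes a protease that removes ISG15, 2.03-fold (adjusted p = 0.00047). Rtp4 had signals of 32.5 ± 8.11 in wild-type and 87.9 ± 22.5 in transgenic mice (SD, n = 9 each), with all 9 transgenic mice above all wild-type mice. Among transcriptional regulators, Skor1 rose 2.53-fold (adjusted p = 0.011), the homeobox gene Uncx 2.43-fold (adjusted p = 0.0005), Onecut2 1.99-fold (adjusted p = 1.9e-06) and the Polycomb-related gene Sfmbt2 1.94-fold (adjusted p = 1.9e-05). Crybb3, a lens crystallin gene, rose 2.22-fold, Gm2102 2.09-fold, the DNA repair gene Brca1 1.98-fold and Adamts18, a secreted metalloprotease gene, 1.90-fold, with adjusted p-values of 0.0085, 0.00013, 3.6e-05 and 0.018.

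Striatal genes fell together. Of 40 measured genes of striatal medium spiny neurons, 34 were lower in transgenic mice and 0 higher (35 lower when adjusted over the list alone), with a median log2 fold change of -0.58 (camera adjusted p = 2.4e-30, and adjusted p = 0.011 with an estimated correlation). Besides Penk and Ppp1r1b, the leading members were Kcnip2, a subunit of A-type potassium channels (2.47-fold lower), and the sodium channel subunit gene Scn4b (2.36-fold lower). Of 24 neuropeptide genes, 15 were lower and 0 higher (20 lower adjusted over the list alone), with a median of -0.63 (camera adjusted p = 8.7e-19). Sst, the somatostatin precursor of cortical and striatal interneurons, fell from 869 ± 138 to 423 ± 58.2 (SD, n = 9 each, adjusted p = 1.1e-06). Without the 3 wild-type samples low in Gabra6 the median was -0.48 for the striatal list and -0.52 for the neuropeptides.

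Immediate early genes, which neurons transcribe when active, were lower for 21 of 29 members and higher for 0 (23 lower adjusted over the list alone, median -0.65, camera adjusted p = 6.6e-19). Egr3 fell 2.03-fold (adjusted p = 1.6e-07), Fosl2 2.04-fold (adjusted p = 9.4e-06), the orphan nuclear receptor gene Nr4a2 1.57-fold (adjusted p = 3.2e-05) and the postsynaptic scaffold gene Homer1 1.5-fold (adjusted p = 2.7e-05). Markers of cortical and hippocampal projection neurons were lower for 16 of 22 (18 adjusted over the list alone, median -0.52, camera adjusted p = 4.6e-16). Lamp5 fell 2.09-fold, Itpka, an inositol trisphosphate kinase of dendritic spines, 2.18-fold, Cckbr 1.84-fold and Nrn1 1.48-fold, with adjusted p-values of 8.1e-09, 2.7e-07, 2.6e-05 and 9.6e-07. These lists also passed with an estimated correlation, with adjusted p-values of 0.005 for the neuropeptides, 0.011 for the immediate early genes and 0.005 for the projection neurons. Without the 3 wild-type samples low in Gabra6 the median was -0.52 for the immediate early genes and -0.45 for the projection neurons.

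Calcium signalling genes were lower for 23 of 37 members and higher for 1, the calcium channel gene Cacna1a, named after its value was seen (26 lower and 2 higher adjusted over the list alone, median -0.34, camera adjusted p = 6.1e-19). The calmodulin-binding gene Pcp4 fell from 3140 ± 197 to 1750 ± 137 (SD, n = 9 each, adjusted p = 2e-08), the kinase gene Camkk2 fell 1.84-fold and Cacng3, an auxiliary subunit of AMPA receptors, 1.77-fold. Potassium channel genes were lower for 19 of 34 (24 adjusted over the list alone, median -0.35, camera adjusted p = 2.1e-15), led after Kcnip2 by Kcnh3, Kcnab1 and Kcnma1 at 1.87-fold, 1.35-fold and 1.41-fold. Glutamate receptor genes were lower for 9 of 20 (12 adjusted over the list alone, median -0.21, camera adjusted p = 1e-06), with Grm2 and Grm3 each 1.58-fold lower, Gria3 1.35-fold lower and Grin2b 1.48-fold lower. The other Grin2b probe sets had a median log2 fold change of 0.066, in the opposite direction. Without the 3 wild-type samples low in Gabra6 the list median was -0.32 for calcium signalling and -0.29 for potassium channels. Of the 20 glutamate receptor genes 5 were lower without the 3 wild-type samples low in Gabra6, with a median of -0.16.

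GABA synapse genes were lower for 8 of 18 (9 lower and 1 higher, Gabra6, adjusted over the list alone, median -0.17, camera adjusted p = 4.6e-05), including the GABA transporter gene Slc6a11 (1.66-fold), the receptor subunit gene Gabrd (1.56-fold), the GABA-synthesising enzyme gene Gad1 (1.28-fold) and Gabbr1 (1.24-fold). Without the 3 wild-type samples low in Gabra6, 5 of 18 were lower with a median of -0.08, and Gabra6 itself went from a log2 fold change of 2.19 ± 0.88 (SE) to -0.03 ± 0.13. Synaptic vesicle genes were lower for 11 of 29 (12 adjusted over the list alone, median -0.17, camera adjusted p = 2.8e-08), led by Bsn, Rph3a, Cplx2 and Sv2b at 1.43-fold, 1.51-fold, 1.42-fold and 1.29-fold, and for 6 without those samples (median -0.15). Cholesterol biosynthesis genes were lower for 10 of 20 (16 adjusted over the list alone, median -0.26, camera adjusted p = 2.8e-08). Among these were Hmgcs1, which encodes an enzyme early in the pathway (1.26-fold lower), and Sqle, Fdft1 and Msmo1 (1.25-fold, 1.36-fold and 1.38-fold lower). With an estimated correlation, the adjusted p was 0.005 for calcium signalling and for potassium channels, 0.011 for glutamate receptors, 0.01 for GABA synapse, and 0.021 for synaptic vesicle and for cholesterol genes.

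Of 23 measured astrocyte markers 14 were lower and 2 higher (17 and 2 adjusted over the list alone, median -0.29, camera adjusted p = 1.6e-07, and adjusted p = 0.014 with an estimated correlation). Mt1, a metallothionein gene, fell 1.49-fold, the glutamate transporter gene Slc1a2 1.44-fold, the connexin gene Gja1 1.32-fold and Fgfr3 1.30-fold. The 2 higher members, named after their values were seen, were Vim, which encodes vimentin (log2 fold change 0.67 ± 0.10 SE), and S100b (0.44 ± 0.09 SE). Thalamus and midbrain markers were lower for 12 of 25 (13 lower and 2 higher adjusted over the list alone, median -0.33, camera adjusted p = 1.4e-06, and adjusted p = 0.032 with an estimated correlation). Besides Slc6a3 these included Prkcd, Rgs16 and Ramp3, which fell 2.10-fold, 2.18-fold and 1.58-fold.

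Meningeal and fibroblast markers were higher for 7 of 16 and lower for 0 (10 higher adjusted over the list alone, median 0.29, camera adjusted p = 3.8e-05). With an estimated correlation the adjusted p was 0.059. Igfbp2 rose 1.46-fold (adjusted p = 1.4e-05), the small proteoglycan genes Fmod 1.54-fold (adjusted p = 3.5e-05) and Ogn 1.49-fold (adjusted p = 0.0012), and Igf2 1.34-fold (adjusted p = 0.0011). Proteasome genes were higher for 6 of 31 (10 adjusted over the list alone, median 0.09, camera adjusted p = 0.0035, and adjusted p = 0.38 with an estimated correlation), by 1.16-fold for Psmd3, 1.12-fold for Psma1, 1.10-fold for Psma4 and 1.09-fold for Psmc2. The other Psma1 probe sets had a median log2 fold change of -0.035, and without the 3 wild-type samples low in Gabra6 1 of the 31 genes, Psmc2, was higher, with a median of 0.08. Hypothalamus and pituitary markers were lower for 4 of 12 (5 adjusted over the list alone, camera adjusted p = 0.00027, and adjusted p = 0.068 with an estimated correlation), namely Pmch, Avp, Trh and Cartpt, a neuropeptide gene that fell 2.21-fold. Growth hormone stood apart in 2 transgenic samples of this comparison.

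Olfactory bulb markers were lower for 3 of 11 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0025, and adjusted p = 0.29 with an estimated correlation). These were Trh, the dopamine-synthesising enzyme gene Th (1.96-fold) and the homeobox gene Lhx2 (1.35-fold), while Calb2 had a log2 fold change of 0.46 (adjusted p = 0.063), and 2 wild-type samples were high in the olfactory bulb gene Cdhr1. The median of this list was -0.48 with all samples and -0.17 without the 3 wild-type samples low in Gabra6. Oligodendrocyte markers were lower for 7 of 22 and higher for 1 (7 lower and 3 higher adjusted over the list alone), and the list did not pass (camera adjusted p = 0.077), whereas it did without those 3 samples (camera adjusted p = 0.019, and adjusted p = 0.22 with an estimated correlation), as it did with fry (adjusted p = 0.014) and at 27 weeks (camera adjusted p = 0.028, and adjusted p = 0.28 with an estimated correlation). The carbonic anhydrase gene Car2 fell from 1660 ± 110 to 1060 ± 45.1 (SD, n = 9 each, adjusted p = 7.1e-08), and Fa2h, Ugt8a and Aspa fell 1.53-fold, 1.31-fold and 1.24-fold. The higher member, named after its value was seen, was the transcription factor gene Olig1 (log2 fold change 0.25, adjusted p = 0.0049). Heat shock and chaperone genes did not pass as a list (4 lower and 1 higher of 30, the same numbers adjusted over the list alone, camera adjusted p = 0.41). The median of the list was 0.01, whereas its mean of -0.05 and its test pointed down, and 2 were lower and 0 higher without those 3 samples. Hspa1b, an inducible HSP70 gene, fell 2.21-fold (adjusted p = 1.7e-06), Dnajb5 1.42-fold and Hsph1 1.17-fold, and the chaperonin gene Cct3 rose 1.17-fold. The other lower member, Hspa1a, named after its value was seen, fell by 0.32 log2 units (adjusted p = 0.026).

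Oxidative phosphorylation genes were higher for 3 of 52 (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.11). Only 1 was higher without the 3 wild-type samples low in Gabra6. The list did pass upward with quantile normalization (camera adjusted p = 0.0039), and by camera it passed downward at 18 weeks (adjusted p = 0.022, but upward with adjusted p = 0.18 after quantile normalization) and upward at 22 and 27 weeks (adjusted p = 0.0016 and 0.0014). With an estimated correlation it passed at no age (adjusted p = 0.63, 0.46 and 0.42), and its medians at the 3 ages were -0.04, 0.09 and 0.07. Ndufa1 rose 1.12-fold, Atp5g1 1.15-fold and Uqcrb 1.10-fold, and Ndufv2 had a log2 fold change of 0.12 (adjusted p = 0.052). The other Atp5g1 probe sets had a median of -0.702, in the opposite direction. Endothelial markers were higher for 2 of 15, Slco1a4 (1.40-fold) and Itm2a (1.18-fold), and lower for 1, Slco1c1 (1.24-fold), with the same numbers adjusted over the list alone (camera adjusted p = 0.82), and Cldn5 had a log2 fold change of -0.23 (adjusted p = 0.11). None of 23 microglia markers passed (camera adjusted p = 0.65), with log2 fold changes of -0.11 for Cx3cr1, 0.21 for Ptprc, 0.16 for Ly86 and -0.31 for Olfml3. None of 19 choroid plexus and ependyma markers passed (camera adjusted p = 0.65), with 0.31 for Sostdc1, 0.32 for Otx2, 0.45 for Slc4a5 and -0.30 for Ccdc153. Nor did any of 5 HOX genes (camera adjusted p = 0.41; Hoxb5 0.58, Hoxb2 0.54, Hoxc4 0.43, Hoxb3 0.31) or of 3 blood cell markers (camera adjusted p = 0.83; S100a8 0.55, Alas2 -0.47, Hbb-b2 -0.09). For these 4 lists the count adjusted over the list alone was also 0.

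Cerebellum markers had a median log2 fold change of 0.37, with 1 higher and 2 lower of 18 (1 and 3 adjusted over the list alone, camera adjusted p = 0.77), in a comparison that held the 3 wild-type samples low in Gabra6. The metabotropic glutamate receptor gene Grm4 and Cdh22 were 1.45-fold and 1.19-fold lower (adjusted p = 0.024 and 0.036), Barhl1 was 1.44-fold higher (adjusted p = 0.049), and Rgs8 had a log2 fold change of -0.54 (adjusted p = 0.051). Without those 3 samples the median was -0.54 and 9 of the 18 genes were lower (camera adjusted p = 1.1e-09, and adjusted p = 0.042 with an estimated correlation). With all samples the list passed upward at 22 weeks and downward at 27 weeks (camera adjusted p = 0.027 and 0.0038, and adjusted p = 0.57 and 0.49 with an estimated correlation).

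**Figure D3:**
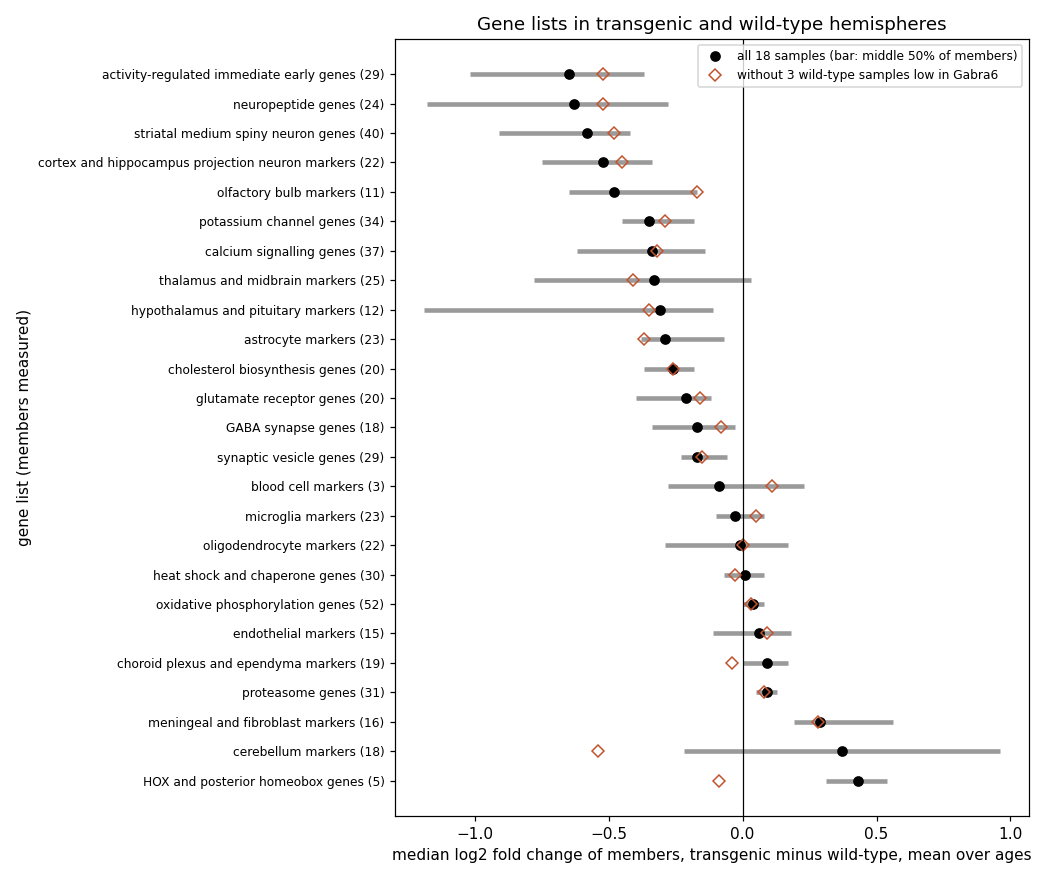
Median log2 fold change of the members of each gene list, transgenic minus wild-type, averaged over the 3 ages. Black points are medians over all 18 samples, grey bars the middle 50% of members, open diamonds the medians without the 3 wild-type samples low in Gabra6, and the number of measured members stands in parentheses. The cerebellum list moves from 0.37 to -0.54 when those samples are left out, and the striatal list from -0.58 to -0.48.

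In all, limma called 4281 of 27022 probe sets between genotypes at an adjusted p below 0.05, 2180 higher and 2101 lower in transgenic mice, which named 2928 genes, 18 of them with probe sets called in both directions. The median size of a called change was 0.33 log2 units, and 16 of the 25 lists passed, 14 down and 2 up. With an estimated correlation 12 passed, all of them down, and the proteasome, meningeal and fibroblast, hypothalamus and pituitary, and olfactory bulb lists did not. Without the 3 wild-type samples low in Gabra6, 2278 probe sets were called, 978 higher and 1300 lower, of which 878 and 1140 were also called with all samples, and all 4281 kept their sign. Mir1931, Ifi27l2a and Adamts18 then no longer passed (adjusted p = 0.078, 0.058 and 0.19), with log2 fold changes of -1.32 against -1.34, 1.07 against 1.35 and 0.48 against 0.92, nor did the list members Cacna1a, Olig1, Hspa1a, Gria3, Cct3, Hsph1, Uqcrb, Atp5g1, Psmd3, Psma1, Psma4, Cdh22, Barhl1 and Lhx2 (adjusted p from 0.052 for Cacna1a to 0.27 for Barhl1). Skor1 still passed but went from 1.34 to 0.59 (adjusted p = 0.049), and Dusp5 went from -1.45 to -2.04. Among the 4281, leaving out the 3 samples moved the median change from 0.284 to 0.263 for the higher and from -0.391 to -0.347 for the lower probe sets. That fit shares all its samples with the main one, so signs kept here and at single ages are not independent evidence. A 1.5-fold minimum left 557 probe sets, 137 higher and 420 lower.

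At 18 weeks the genes that were lower included 3 neuropeptide genes, a striatal gene and the dopamine transporter gene. Pmch fell from 512 ± 116 to 132 ± 26.5 (SD, n = 3 each, log2 fold change -1.91 ± 0.18 SE, limma adjusted p = 1.4e-05), Ppp1r1b from 446 ± 36.7 to 148 ± 24.2 (adjusted p = 4.4e-05) and the dopamine transporter gene Slc6a3 from 67.8 ± 7 to 18.1 ± 9.53 (adjusted p = 0.0018). Avp fell 3.84-fold and Trh 2.95-fold (adjusted p = 0.022 and 0.043). Among the rises, the interferon-induced genes Rtp4 and Oasl2 rose 2.41-fold and 2.24-fold (adjusted p = 0.016 and 0.018), Rps6, a ribosomal protein gene, 2.39-fold, Dand5 2.06-fold and Polr2a, the largest subunit of RNA polymerase II, 2.04-fold. Of the 40 striatal genes 17 were lower (27 adjusted over the list alone, median -0.59, camera adjusted p = 4.4e-28, and adjusted p = 0.02 with an estimated correlation), as were 16 of 37 calcium signalling genes (22 adjusted over the list alone, median -0.36, camera adjusted p = 4.6e-21, and adjusted p = 0.0064 with an estimated correlation). Without the sample low in Gabra6 at this age and the 2 at 22 weeks, 11 striatal genes (median -0.45) and 12 calcium signalling genes (median -0.36) were lower. Immediate early genes were lower for 4 of 29 at this age (15 adjusted over the list alone, median -0.52, adjusted p = 0.037 with an estimated correlation), and for 2 without those samples (median -0.47, adjusted p = 0.044 with an estimated correlation).

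The comparison at 18 weeks called 534 probe sets, 158 higher and 376 lower, and 210 without the samples low in Gabra6, when all 534 kept their sign. Avp, Trh, Rtp4, Oasl2 and Polr2a then no longer passed (adjusted p = 0.13, 0.17, 0.067, 0.073 and 0.14), at log2 fold changes of -1.65, -1.39, 1.26, 1.10 and 0.92 against -1.94, -1.56, 1.27, 1.16 and 1.03 with all samples. The count rested on single mice, with 173, 301 and 258 calls without wild-type replicates 1, 2 and 3 (30, 71 and 67 of them higher) and 392, 265 and 401 without transgenic replicates 1, 2 and 3 (110, 63 and 72 higher). Of the 10 genes only Pmch, Ppp1r1b and Slc6a3 passed with each of these mice left out, and the 6 mice of that age alone gave 81.

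At 22 weeks the genotype difference rested on 2 transgenic mice as titled, and 2 of the 3 wild-type samples were low in Gabra6. Pmch fell from 508 ± 108 (SD, n = 3) to 112 ± 0.212 (SD, n = 2), a log2 fold change of -2.11 ± 0.20 (SE, limma adjusted p = 3.4e-05). The dopamine transporter gene Slc6a3 fell 4.10-fold (adjusted p = 0.00093), and the activity-induced transcription factor genes Egr2 and Npas4 fell 4.60-fold and 3.76-fold (adjusted p = 0.0039 and 0.048). Ces5a, a carboxylesterase gene, fell 3.78-fold (adjusted p = 0.041). The largest rises were in the homeobox genes Uncx (4.27-fold, adjusted p = 0.0082) and Tlx3 (2.66-fold, adjusted p = 0.027), and in Mndal, A930017K11Rik and Spag6l (2.61-fold, 2.46-fold and 2.31-fold). Immediate early genes were lower for 13 of 29 (19 adjusted over the list alone, median -0.79, camera adjusted p = 3.8e-19, and adjusted p = 0.01 with an estimated correlation) and striatal genes for 22 of 40 (33 adjusted over the list alone, median -0.81, camera adjusted p = 4.5e-31, and adjusted p = 0.01 with an estimated correlation). Without the samples low in Gabra6, which left 1 wild-type mouse at this age, 1 of 29 immediate early genes was lower with a median of -0.58 (adjusted p = 0.044 with an estimated correlation), and 4 of 40 striatal genes with a median of -0.49 (adjusted p = 0.02 with an estimated correlation).

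The comparison at 22 weeks called 798 probe sets, 236 higher and 562 lower, but 46 without the samples low in Gabra6, when all 798 kept their sign and only Pmch among these 10 genes still passed (adjusted p = 0.0046). The log2 fold change went from -1.92 to -1.95 for Ces5a, -2.03 to -1.75 for Slc6a3, -2.20 to -1.60 for Egr2 and 2.09 to 1.36 for Uncx, and from -1.91 to -1.02 for Npas4, 1.41 to 0.69 for Tlx3, 1.39 to 0.68 for Mndal, 1.21 to 0.69 for Spag6l and 1.30 to 0.33 for A930017K11Rik. Leaving out single mice gave 1344, 399 and 259 calls without wild-type replicates 1, 2 and 3, and 227 and 156 without transgenic replicates 1 and 2, while counting 1 of the 27-week transgenic mice as 22 weeks gave 1326 to 1647.

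At 27 weeks every sample had cerebellar signal. Pmch fell from 385 ± 21.9 (SD, n = 3) to 95.5 ± 14.7 (SD, n = 4), a log2 fold change of -1.96 ± 0.17 (SE, limma adjusted p = 1.9e-05). The neuropeptide gene Cartpt fell from 181 ± 31.8 to 61.6 ± 28.4 (adjusted p = 0.0032), the striatum-enriched gene Lrrc10b fell 2.80-fold (adjusted p = 0.0032), and Dusp5 and Avp fell 4.90-fold and 2.89-fold (both adjusted p = 0.048). The transcription factor gene Onecut2 rose from 18.5 ± 2.43 to 67.5 ± 7.96, 3.04-fold (adjusted p = 2.6e-05), and the interferon-induced gene Rtp4 from 29.0 ± 8.47 to 93.3 ± 14.1 (adjusted p = 0.002). Gapdhs, a sperm glycolytic enzyme gene, Gm2102 and Slc5a5, the sodium-iodide symporter gene, rose 2.68-fold, 2.62-fold and 2.55-fold.

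Striatal genes at 27 weeks were lower for 13 of 40 members (26 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 3.7e-21, and adjusted p = 0.021 with an estimated correlation), and neuropeptide genes for 10 of 24 (14 lower and 1 higher adjusted over the list alone, median -0.65, adjusted p = 0.0059 with an estimated correlation). Astrocyte markers were lower for 10 of 23 (11 adjusted over the list alone, median -0.39, adjusted p = 0.0059 with an estimated correlation), and meningeal and fibroblast markers were higher for 4 of 16 (7 adjusted over the list alone, median 0.38, adjusted p = 0.021 with an estimated correlation). The comparison called 641 probe sets, 193 higher and 448 lower. It called 253 to 425 without wild-type replicate 1, 2 or 3 or transgenic replicate 1, 3 or 4 (312, 253, 340, 353, 425 and 409), 259 without the 2 samples high in growth hormone, and 396 with transgenic replicate 1 counted as 22 weeks.

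Across ages, 200 probe sets passed at 18, 22 and 27 weeks, each in 1 direction, 169 lower and 31 higher in transgenic mice. The number was 36 without the 3 wild-type samples low in Gabra6, 31 lower and 5 higher, of which 34 were among the 200. Of the 534 probe sets called at 18 weeks, 97.9% had the same sign at 27 weeks, where none of the mice were shared. The calls used a spread estimated from all 18 mice, and the share of equal signs over all probe sets was not computed. Log2 fold changes at 18 and 27 weeks had a Pearson correlation of 0.41 across probe sets, which are not independent replicates, and those at 18 and 22 weeks one of 0.47, against 0.40 and 0.27 without the 3 samples.

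Whether the genotype difference depended on age was tested directly. No probe set passed (limma, 0 of 27022, with 1047 at an unadjusted p below 0.05 where 1351 are expected by chance). The 5 genes with the smallest p were Cacng3 (adjusted p = 0.51) and Slco5a1, Zfp729a, Gm10037 and Onecut2 (adjusted p = 1 each). Cacng3 had signals of 342 ± 21.9, 302 ± 16.2 and 233 ± 8.70 in wild-type mice at 18, 22 and 27 weeks and 144 ± 15.4, 164 ± 2.26 and 176 ± 19.5 in transgenic mice (SD, n = 3, 3, 3, 3, 2 and 4). Onecut2 had 42.3 ± 3.43 at 18 weeks and 67.5 ± 7.96 at 27 weeks in transgenic mice. Its wild-type signals ranged from 21 to 25.8 at 18 weeks, 28.3 to 42.3 at 22 weeks and 15.9 to 20.7 at 27 weeks. In the simulated data changes of 1 log2 unit were recovered in 40% of cases for this test.

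Age within wild-type mice gave 1 probe set past the threshold, for the growth factor gene Fgf1 (limma adjusted p = 0.0235, with 1879 at an unadjusted p below 0.05). This probe set, named because it was the only one, had signals of 3.60 ± 0.889 at 18 weeks, 24.1 ± 4.99 at 22 weeks and 24.3 ± 7.31 at 27 weeks (SD, n = 3 each), whereas the stronger Fgf1 probe set had 450 ± 41.2, 458 ± 57.7 and 507 ± 37.7 (adjusted p = 0.835). Gapdhs (adjusted p = 0.27) and Cacng3, Fastkd3, Dusp14 and Nek2 (adjusted p = 0.55 each) came next and did not pass. Dusp14, a dual-specificity phosphatase gene, had signals of 307 ± 20.9, 408 ± 31.6 and 308 ± 15.4 at the 3 ages, the middle age being the one with 2 samples low in Gabra6. Without those samples the count was 0 (1347 at an unadjusted p below 0.05), and without 22-week wild-type replicate 1 it was 89. It was also 0, with 1570 to 1999 at an unadjusted p below 0.05, without 18-week wild-type replicate 1, 2 or 3, 22-week wild-type replicate 3, 27-week wild-type replicate 1 or 2, 18-week transgenic replicate 2, 22-week transgenic replicate 1 or 2, or 27-week transgenic replicate 2 or 4.

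Age within transgenic mice gave 0 probe sets (limma, with 1296 at an unadjusted p below 0.05). The smallest adjusted p-values of named genes were 0.13 for Rgs5, a pericyte gene, 0.41 for Cep164, Erich3 and Adss, and 0.42 for Msi1. Rgs5 had signals of 479 ± 57.3 (SD, n = 3) at 18 weeks, 927 ± 16.0 (SD, n = 2) at 22 weeks and 567 ± 71.5 (SD, n = 4) at 27 weeks. Without the 3 wild-type samples low in Gabra6, which enter this test only through the shared spread, 5 probe sets passed. Leaving out 18-week wild-type replicate 3 gave 5, and leaving out 22-week wild-type replicate 1 or 3 gave 4 each.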

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

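The splits of the samples were planned, and the tests of the 3 wild-type samples low in cerebellar markers were chosen after the results were seen. For the mean over ages the grouping by genotype called 4281 probe sets, and it was 1 of 100 drawn splits within ages to call as many, the highest of the others calling 15, so chance is excluded at the 0.05 level. At 27 weeks the real grouping called 641 and was 1 of 35 splits to call as many, the highest other calling 18, which also excludes chance at that level. At 18 weeks the real grouping called 534 and the highest other called 1, but only 10 splits exist, too few for a share under 0.05. For age in wild-type mice 22 of 100 drawn splits called at least the 1 probe set of the real ages, so chance is not excluded. The highest called 516 and put all 3 samples low in Gabra6 in 1 group, which points to a structure of the samples other than age.

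Among the 4 transgenic mice of 27 weeks, 159 values of named genes and gene lists were searched for a mouse that stood apart from the other 3. This found 8, and 8 are expected by chance. Replicate 1 was low for Ppp1r1b (127 against 178 to 190), Rph3a (348 against 382 to 388) and Nrn1 (668 against 751 to 757). Replicate 2 was low for Ndufv2 (1624 against 1800 to 1832) and Hoxc4 (10.7 against 32.0 to 33.8) and high for Rgs16 (34.5 against 25.6 to 26.6). Replicate 3 was low for Slc6a3 (14.8 against 24.2 to 25.6), and replicate 4 was low for Zfp729a (35.4 against 61.6 to 63.3). No named gene passed the test for a genotype difference that depends on age.

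The count of 798 probe sets at 22 weeks may reflect the missing cerebellar signal in 2 of the 3 wild-type samples. With 1 wild-type mouse left out in each case, the comparison called 1344 when the remaining pair both lacked cerebellar signal and 399 or 259 when 1 of the remaining pair had it. The mouse left out also changes the shared spread, which can move these counts. Leaving out 22-week wild-type replicate 1, 2 or 3 moved the count from 534 to 629, 480 or 533 at 18 weeks. At 27 weeks, where those mice are likewise not compared, it went from 641 to 714, 572 or 632. These moves were smaller than those at 22 weeks, which argues against the shared spread alone as the source of the gap at 22 weeks. Whether the tissue or another difference between these mice made the rest of that gap cannot be told from single mice left out. All 798 kept their sign without the 3 samples, with medians of -0.60 against -0.76 for the lower and 0.51 against 0.60 for the higher. For the striatal genes the median log2 fold change went from -0.59 to -0.45 at 18 weeks without the 3 samples. At 22 weeks, with 1 wild-type mouse left, it went from -0.81 to -0.49, so these samples added to the difference at those ages. They do not alone account for the lower striatal genes, whose median was -0.45 at 27 weeks, where no sample lacked cerebellar signal (camera adjusted p = 0.021 with an estimated correlation). The striatal genes thus differed between the genotypes. Whether the transgene or another difference between the mice, which the labels do not record, caused this stays open.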

How the results depend on the processing

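The 3 settings on samples low in Gabra6 or high in growth hormone were added after the data were seen. For the mean over ages (4281) the count was 557 with a 1.5-fold minimum, 2699 with 1 probe set per gene, 2278 without the 3 wild-type samples low in Gabra6, 2580 with a term for them, and 3005 to 4655 with each sample left out. At 18 weeks (534) it was 352 with no filter, 320 without the variance trend, 275 with a 1.5-fold minimum, 81 with the mice of that age alone, 210 without the 3 samples, 328 with a term for them, and 173 to 629 with each sample left out. At 22 weeks (798) it was 1620 with array weights, 183 with the mice of that age alone, 1647, 1326, 1600 and 1362 with 27-week transgenic replicate 1, 2, 3 or 4 counted as 22 weeks, 46 without the 3 samples, 159 with a term for them, and 156 to 1344 with each sample left out, 1 sample then standing alone in some fits and assumed to vary like the others. At 27 weeks (641) it was 1132 with array weights, 319 with a 1.5-fold minimum, 396 with transgenic replicate 1 counted as 22 weeks, 259 without the 2 samples high in growth hormone, and 253 to 799 with each sample left out.

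The interaction (0) gave 1 probe set with array weights (1498 at an unadjusted p below 0.05) and 0 with each sample left out. Age in wild-type mice (1) gave 0 with the offset multiplied by 4, with no filter, with the filter at the 60th percentile, with 1 probe set per gene and without the 3 samples (1863, 2890, 1343, 991 and 1347 unadjusted), and 0 to 89 with each sample left out. Age in transgenic mice (0) gave 5 without the 3 samples, 2 with a term for them, and 0 to 5 with each sample left out. The gene lists that passed (16) numbered 12 with an estimated correlation, 17 with fry, which added the oligodendrocyte list, 17 with quantile normalization, which added oxidative phosphorylation, and 18 without the 3 samples, which added the oligodendrocyte and cerebellum lists. The cause of these moves was not tested, except that a fold minimum lowers a count by construction.

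Of 157 results for named genes, 122 had passed, and 3 of these turned their direction, all by the median of the gene's other probe sets (Grin2b 0.066, Atp5g1 -0.702, Psma1 -0.035). For 17 other values that median lay further from the gene's own value than the residual SD of its shown probe set. Under the other planned settings 102 of 2119 values no longer passed and 21 newly passed, with each sample left out 177 of 2826 no longer passed and 15 newly passed, and under the added settings 62 of 471 no longer passed and 5 newly passed. The genes specific to a sex only check the samples and were left out. Without the 3 samples the median of the list turned for HOX genes (-0.09), microglia (0.05), choroid plexus (-0.041), blood cells (0.112), cerebellum (-0.543) and heat shock genes (-0.03 from 0.01, with the test downward in both). Without the 3 samples and with a term for them, genes that had not passed turned too, Hoxb5 (-0.155 and -0.039), Hoxb3 (-0.092 and -0.1), Hoxc4 (-0.09 and -0.05), Sostdc1 (-0.044 and -0.079) and Hbb-b2 (0.112 and 0.026, and -0.219 to 0.005 with each sample left out). No paired analysis was possible because the replicate numbers follow the order of deposit and pair no mice. Signal over background limits the fold changes of weak probe sets, which the offset of 5.4 makes smaller.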

Other observations

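The microglia and the meningeal and fibroblast lists were planned. Their use here and all other tests in this part were chosen after the results were seen. Genes induced by interferon were higher in transgenic hemispheres as a group. Of 48 such genes, listed after Rtp4, Oasl2, Usp18 and Ifi27l2a had been seen to rise, 39 were measured, 27 were higher and 0 lower, and all 39 had a positive log2 fold change, with a median of 0.53 (camera p = 1.5e-15, and p = 0.0049 with an estimated correlation). Parp12 rose by 0.92 ± 0.08 log2 units (SE, limma with Benjamini-Hochberg adjusted p = 8e-07), Ifitm3 by 0.64 ± 0.09 (adjusted p = 0.00013), Xaf1 by 0.80 ± 0.12 (adjusted p = 0.00018), the transcription factor gene Irf7 by 0.71 ± 0.13 (adjusted p = 0.001) and B2m, which encodes the light chain of MHC class I, by 0.33 ± 0.11 (adjusted p = 0.04, but 0.12 at a rise of 0.31 without the 3 wild-type samples low in Gabra6). At 18, 22 and 27 weeks the median was 0.41, 0.58 and 0.58 with 6, 5 and 13 genes higher, and without those 3 samples it was 0.36, 0.49 and 0.58 with 1, 0 and 10 higher (camera p = 0.051, 0.042 and 0.0061 with an estimated correlation). Among the immunoproteasome genes of this list, Psmb8 rose by 0.50 ± 0.09 (adjusted p = 0.0014), and Psmb9 differed by 0.24 ± 0.13 (adjusted p = 0.21).

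A raised interferon response in the transgenic mice is a hypothesis for this pattern. The genes that had drawn attention do not alone carry it, since the 35 members without them had a median of 0.50 (camera p = 0.0045 with an estimated correlation). Because the whole list was written after the data were seen, this does not exclude a choice of members that had risen. More microglia in the transgenic samples would raise microglia markers alike, but the upper quartile of their log2 fold changes was 0.08, and 0 of 23 passed, although their median at 27 weeks was 0.11 (camera adjusted p = 0.057). Without the 3 wild-type samples low in Gabra6 the median of the interferon list was 0.45 and 21 of 39 genes were higher (camera p = 0.012 with an estimated correlation). More meningeal tissue was not tested and stays open, since meningeal and fibroblast markers rose too (7 of 16 higher, 0 lower, median 0.29, camera adjusted p = 0.059 with an estimated correlation). Infection, housing and array batch, which the sources used here do not record, also stay open. So does a difference in genetic background between the mice, which was not tested. Whether the transgene may account for the interferon pattern is therefore open.

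Cerebellar genes moved apart in the transgenic mice once the samples without cerebellar signal were set aside. Among the 15 samples with such signal, Pcp2 differed by -0.80 ± 0.10 log2 units (SE, limma with Benjamini-Hochberg adjusted p = 0.00029), Car8 by -0.77 ± 0.13 (adjusted p = 0.0015), Cbln1 by -0.58 ± 0.10 (adjusted p = 0.0019) and Cbln3 by -0.56 ± 0.10 (adjusted p = 0.0022). Gabra6 differed by -0.03 ± 0.13, Fat2 by -0.03 ± 0.13, Neurod1 by -0.06 ± 0.08 and En2 by 0.11 ± 0.10. Pcp2 and Car8 are genes of Purkinje cells, while Cbln3, Gabra6 and Fat2 are genes of granule cells. Among the 7 mice of 27 weeks alone, Car8, Cbln3 and Cbln1 differed by -1.06 ± 0.18, -0.73 ± 0.13 and -0.63 ± 0.13 (limma adjusted p = 0.014, 0.015 and 0.027). Pcp2 had 1440 ± 78.0 (SD, n = 3) in wild-type and 719 ± 128 (SD, n = 4) in transgenic mice. Gabra6, Neurod1, Fat2 and En2 differed by -0.18 ± 0.13, -0.21 ± 0.08, -0.01 ± 0.17 and 0.01 ± 0.14 and did not pass (adjusted p = 0.53, 0.19, 0.98 and 0.98).

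A lower level of some cerebellar transcripts per cerebellum, and not less cerebellum, is a hypothesis for this. Less cerebellar tissue would lower Gabra6 at least as much as the other 7 markers over 4-fold lower in the 3 samples without cerebellar signal. Gabra6 had the largest drop of the 8 there (-6.67 log2 units, against -2.25 for Neurod1). The mean of the other 7 instead differed by -0.355 log2 units relative to Gabra6, transgenic minus wild-type (two-sided exact permutation within ages, p = 0.0019). This contrast was set after Pcp2, Car8, Cbln1 and Cbln3 had been seen to fall, so its p-value adds no separate support. Neurod1, Fat2 and En2 (-0.06, -0.03 and 0.11) did not fall with them. The choice of samples left out does not account for the fall of Pcp2, which differed by -1.01 ± 0.11 among the 7 mice of 27 weeks alone, where none was left out (limma adjusted p = 0.0023). The fit of all 18 samples, tried first, gave the same -1.01 with an SE of 1.33, because the samples without cerebellar signal widen its spread. A loss of Purkinje cells alone would not lower Cbln3, a granule cell gene that differed by -0.56 ± 0.10, and whether it may account for Pcp2 and Car8, beside the value of -0.355, was not tested.

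For 2 genes the mice fell into a low and a high set, each with mice of both genotypes. For H2-K1, a gene of MHC class I, 5 mice (4 wild-type and 1 transgenic) had signals of 30.2 to 50.2 and the other 13 had 146 to 296. For 1 Prdx2 probe set, 8 mice (7 wild-type and 1 transgenic) had 39.2 to 63.7 and 10 had 268 to 617, whereas another Prdx2 probe set had 1365 to 1796 in all 18 mice. Both genes were chosen after their values were seen, and a difference in genetic background between the mice, which would bear on the genotype comparison of such genes, was not tested.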
